A study of Homo sapiens with 12 samples.

How the data were processed

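Gene-level RNA-seq counts of 12 libraries from HuH-7 cells were analysed, 3 in each of 4 groups: V5 precipitates and inputs of the line with WT HuR and of the line with HuR K120/182R. The deposited values are raw counts per Ensembl gene, 1 set per library and not pooled. Per the labels, the authors made stranded total RNA libraries, demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt, aligned to hg19 with STAR 2.4.0j and counted reads with featureCounts 1.6.4. The annotation release, the strand setting and the handling of reads with several places are not stated there.

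Identifiers were matched to GENCODE release 44 placed on GRCh37, which may differ from the authors' annotation. Of 57773 identifiers 55538 matched, and those without a match held up to 21.0% of a library's counts. Positions are from that annotation. Gene-level totals run from 31774994 to 73149117 per library, and p-values and errors come from the spread between libraries, not from counting error alone. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 13.6 to 203 between pairs.

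Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and Biopython 1.88. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 22984. Counts were normalized by the trimmed mean of M values (TMM; factors 1.32 to 1.78 in precipitates and 0.526 to 0.909 in inputs). All 12 libraries entered 1 robust quasi-likelihood fit in edgeR, with the 4 groups as coefficients and 8 residual degrees of freedom. The common biological coefficient of variation was 0.157. Genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood F-test were called, with no fold limit. The 5 comparisons were each precipitate against its input, the difference of these enrichments, the precipitates with each other and the inputs with each other. Standard errors of log2 fold changes were derived from the F statistic. CPM are counts scaled by the TMM library sizes.

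The tests, the 20 gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule took, from genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and, in the comparisons of 2 groups, complete separation of the libraries, the 10 highest and 10 lowest protein-coding genes and the 5 highest and 5 lowest of other classes, with ELAVL1 always and up to 4 members per list by smallest adjusted p. Genes without a symbol were not to be named, and those that are named, 3 for their difference of enrichments and ENSG00000258486 as the most counted in the inputs, were chosen after their values were seen. The text names fewer than the rule allows, and a few of the results the rule selects are not reported here. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 20 lists within a comparison. Fry asks whether a list's genes move 1 way on balance and does not compare them with other genes. Older gene names were mapped through RefSeq synonyms, a step changed after the first list results had been seen, and names reaching the same gene were counted once, so 18 histones were tested of 39 listed names.

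The alternatives were DESeq2 size factors, total library size, TMM from protein-coding genes, the DESeq2 test, no filter, a stricter filter (50 counts in 3 libraries), only the groups compared, a fold limit of 1 on the log2 scale, the replicate number as a block, a block within line, an estimated correlation, fry, and leaving out each library in turn. Removing the trend of each library with transcript GC content, and testing coding genes only, were chosen after seeing the data. The fit was tested on simulated data with 200 changed genes in 21074, where genes changed by 1 log2 unit were found in 82%, 47% and 84% and those changed by 0.5 in 13%, 2% and 6% for the mutant enrichment, the difference of enrichments and the precipitates. False calls there were 11 of 106, 4 of 53 and 10 of 100.

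Genes that overlap were checked after seeing the data, in a form chosen after looking at the pairs. Noncoding genes lying in exons of abundant coding genes on the opposite strand held counts that scaled with those of the coding gene. Across 138 such pairs, which are not independent replicates, Spearman rho was 0.67 and the median ratio 1.09. Pairs on the same strand scaled less (72 pairs, rho 0.45, median ratio 0.3). Antisense genes thus cannot be relied on as separate, and genes that overlap on the same strand are treated as uncertain too. No genes on the Y chromosome are named.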

Results

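RNA-seq libraries were made from HuH-7 cells, an established human hepatoma line, to compare the RNAs recovered with wild-type (WT) HuR and with a SUMOylation mutant of HuR. HuR is the RNA-binding protein encoded by ELAVL1. It is known for binding AU-rich and U-rich elements of mRNAs. SUMOylation is the attachment of a small ubiquitin-like protein to lysines, and the mutant, K120/182R, carries arginines in place of a pair of lysines. Both lines stably carried a V5-tagged HuR, and RNA was sequenced after RNA immunoprecipitation (RIP) with the tag and from the cells' total RNA (input). There were 4 groups of 3 libraries: WT RIP, mutant RIP, WT input and mutant input. No mock precipitation and no line without the tagged protein are used here, so a level above input was not compared with a background of RNA that sticks to the beads. Per the labels, RIP libraries were made from 16 to 77 ng of RNA and input libraries from 250 ng. Effects of that amount cannot be told apart from precipitation when a precipitate is compared with its input. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The total gene counts of libraries 1, 2 and 3 were 33969067, 49612379 and 43663060 in WT RIP, 45205641, 46424851 and 31774994 in mutant RIP, 52052110, 61004308 and 59034739 in WT input, and 55886447, 73149117 and 63660833 in mutant input.

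The kinds of RNA counted differed between precipitates and inputs. Protein-coding genes outside the mitochondrial genome held 69.8% ± 4.86 (SD, n = 3) of the counts in WT RIP and 66.7% ± 3.73 (n = 3) in mutant RIP, against 33.8% ± 5.52 (n = 3) in WT input and 25.2% ± 1.34 (n = 3) in mutant input. Small structural RNAs, which include the spliceosomal, signal recognition particle and 7SK RNAs, held 13.7% ± 4.02 in WT RIP and 17.3% ± 3.05 in mutant RIP, but 44.01% ± 6.21 in WT input and 49.5% ± 0.781 in mutant input. The most counted gene was RN7SK in each of the 6 RIP libraries (3.33% to 7.68% of counts) and ENSG00000258486, an identifier without an entry in the annotation used, in each of the 6 inputs (up to 19.5%). For want of an entry that identifier is counted in none of these classes, so the share of the class it belongs to is understated. Along the first principal component (60.8% of the variance) precipitates separated from inputs, and along the second (12.6%) the WT line separated from the mutant line. All fold changes below are on the log2 scale, with the standard error (SE) of the fit after ±, and are relative to the typical gene. The genes ranked by fold change had all 3 libraries of 1 group above all 3 of the other, in each comparison of 2 groups. Scaling by the total library size instead moved the median of all genes from 0.06 to 1.12 in the WT enrichment and from 0.07 to 1.38 in the mutant enrichment. That median became 0.25 in the difference of enrichments, −0.17 between the precipitates and −0.43 between the inputs. A value of opposite sign to such a move, and clearly smaller in size, would change sign.

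**Figure D1:**
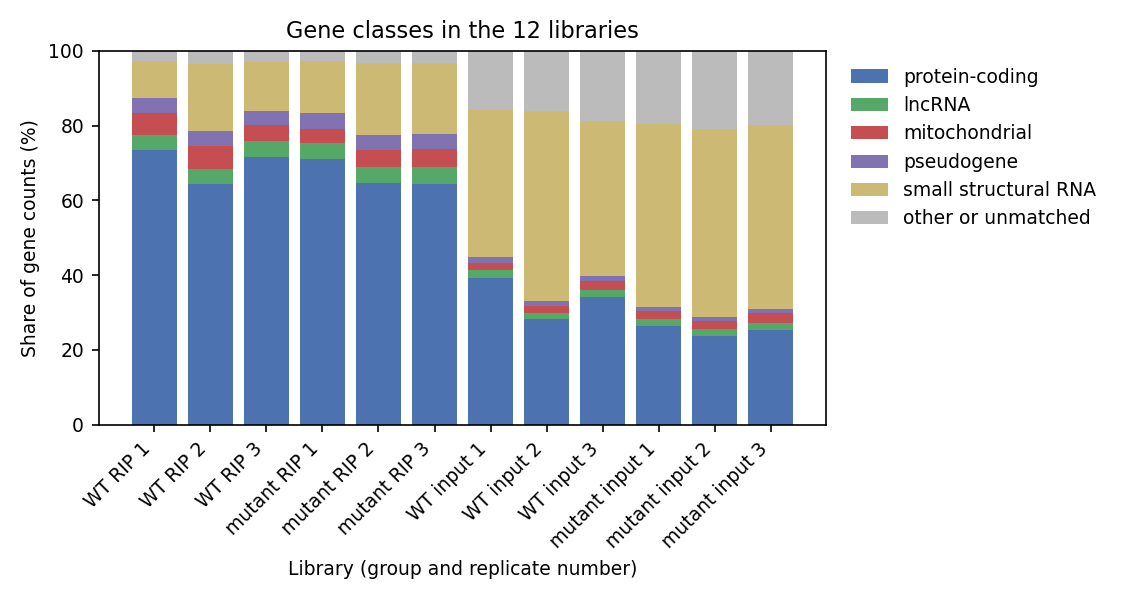
Stacked bars give the share of gene counts (%, from 0 to 100) in each of 6 gene classes, 1 bar for each of the 12 libraries. Protein-coding genes held 64.3% to 73.4% of the counts in the 6 RIP libraries and 23.8% to 39.2% in the 6 inputs.

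ELAVL1 itself (ENSG00000066044, chromosome 19, 8023457 to 8070543 on the minus strand, hg19) did not differ past the threshold between the 2 lines in the main fit. In inputs and in precipitates alike, it was lower in each mutant library than in each WT library. Its normalized level was 58.2 ± 5.32 CPM (library-scaled counts; SD, n = 3) in WT input and 48.4 ± 4.18 (n = 3) in mutant input, a log2 difference of −0.27 ± 0.12 that did not pass the test (adjusted p = 0.14). In the precipitates it stood at 34.5 ± 3.03 CPM for WT and 27.2 ± 3.74 for the mutant, a difference of −0.34 ± 0.12 (adjusted p = 0.0561). Its enrichment did not differ detectably between the lines (−0.07 ± 0.17, adjusted p = 0.915). ELAVL1 RNA was lower in the precipitate than in the input of both lines, by log2 −0.76 ± 0.12 in WT (adjusted p = 1.45e-05) and −0.83 ± 0.12 in the mutant (adjusted p = 3.35e-06), and these 2 differences turned to 0.295 and 0.49 with total library size. The counts are per gene, so RNA of the added tagged gene and of the cells' own ELAVL1 cannot be told apart. The difference between precipitates passed the test with the replicate number as a block (−0.34, adjusted p = 0.0329), with the GC trend removed (−0.34, adjusted p = 0.0195) and without mutant RIP 1 (−0.46), and that between inputs passed it with total library size (−0.72, adjusted p = 0.00277).

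The first comparison asked which RNAs were recovered with WT HuR above or below their level in the same cells. Small nucleolar RNAs (snoRNAs), which guide chemical modification of ribosomal and other RNAs, were the class most often higher in the precipitate: 191 of 302 were higher and 26 lower, with a median log2 fold change of 1.99. Of the snoRNAs in an intron of a coding gene, 109 on the host's strand had a median of 2.08 and 17 on the opposite strand 2.36. Reads of unspliced host RNA cannot be told apart from theirs, here or in the comparisons below. Long noncoding RNAs (1404 of 4523 higher, 514 lower, median 0.48) and pseudogenes (761 of 2617 higher, 250 lower, median 0.53) also leaned to the precipitate, and protein-coding genes to the input (3084 of 14004 higher, 4769 lower, median −0.13). The small Cajal body RNA SCARNA7 (ENSG00000238741, chromosome 3, 160232695 to 160233024) showed the largest increase among noncoding genes named by the fixed rule, 6.64 ± 0.64, from 5.48 ± 1.79 CPM (SD, n = 3) in input to 544 ± 248 in the precipitate. MIR3609 (6.51 ± 0.42), SNORD14E (5.49 ± 0.32), SNORD6 (5.45 ± 0.28) and SNORD2 (4.86 ± 0.64) followed. At the other end stood 4 RN7SL copies and RN7SL2, genes for the RNA of the signal recognition particle, from −6.43 ± 0.49 for RN7SL359P to −6.20 ± 0.37 for RN7SL2. These are near-identical copies that can share reads, and how such reads were counted is not stated, so their separate values are uncertain.

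Among protein-coding genes, the largest increases in the WT precipitate included XKR9, a member of the XK-related membrane protein family (ENSG00000221947, chromosome 8, 71581574 to 71702606; 3.77 ± 0.22), DCDC2B (3.31 ± 0.26), MAN1A2, a Golgi mannosidase (3.23 ± 0.16), and LRRC37A (3.22 ± 0.22). XKR9 went from 1.71 ± 0.131 CPM (SD, n = 3) in input to 23.4 ± 5.64 in the precipitate. LRRC37A2, DNAI4, ARHGAP12, BTBD8 and FAM13B were also among the top 10, at 2.79 to 3.07. The mRNAs most depleted from the precipitate included those of apolipoprotein E (APOE, −3.40 ± 0.18), alpha-1 antitrypsin (SERPINA1, −2.93 ± 0.15), vitronectin (VTN, −2.90 ± 0.16), collagen VI (COL6A1, −3.01 ± 0.21), cathepsin D (CTSD, −2.93 ± 0.15) and PLBD2 (−3.32 ± 0.15). APOE (ENSG00000130203, chromosome 19, 45409048 to 45412650) fell from 302 ± 14.4 CPM in input to 28.6 ± 5.07 in the precipitate. KM-PA-2 (−3.11), PLXNB2 (−2.92) and BOP1 (−2.88) were the remaining members of this set beside WDR74 (−4.07 ± 0.35). WDR74 is uncertain, because the small nuclear RNA gene RNU2-2P lies in its exons and the totals of the 2 genes over the 12 libraries were nearly equal (7174811 and 7159517). DCDC2B shares 33.7% of its exon bases with TMEM234, CTSD shares 22.9% with another coding gene, SNORD2 lies wholly in exons of EIF4A2, and the LRRC37A genes are near-identical copies, so their values are uncertain too.

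Of the 20 gene lists, 6 passed the camera test in the WT enrichment. Genes for secreted and metabolic products of hepatocytes were lower in the precipitate in 25 of 38 members and higher in 1 (26 and 1 adjusted over the list alone; median −0.85; adjusted p = 3.53e-10), and this was the only one of the 6 to hold with an estimated correlation (adjusted p = 0.0194). APOE, SERPINA1, AMBP (−2.77) and prothrombin (F2, −2.33) were its leading members. Nuclear-retained and other long noncoding RNAs were higher in 20 of 24 members and lower in 1 (21 and 1 adjusted over the list alone; median 1.30; adjusted p = 2.39e-10, and adjusted p = 0.14 with an estimated correlation). These included NEAT1, the scaffold of nuclear paraspeckles (1.98 ± 0.13), CRNDE (2.01 ± 0.13), SNHG6 (2.18 ± 0.16) and NORAD (1.63 ± 0.15). SNHG6 shares 58.9% of its exon bases with MCMDC2 on the opposite strand and is uncertain. Glycolytic genes were lower in 16 of 23 and higher in 0 (17 and 0 adjusted over the list alone; median −0.81; adjusted p = 2.67e-05, and adjusted p = 0.241 with an estimated correlation). GPI stood at −1.92, ALDOA at −2.01, GAPDH at −1.83 and ENO1 at −1.50. GAPDH shares 17.6% of its exon bases with an antisense gene and is uncertain. The 0 higher glycolytic members are by edgeR, with 0 also at an unadjusted p under 0.05 and by DESeq2. Genes of the integrated stress and unfolded protein response were lower in 17 of 30 and higher in 5 (the same counts adjusted over the list alone; median −0.45; adjusted p = 5.06e-05, and adjusted p = 0.14 with an estimated correlation). Its leading members CALR (−2.04), HSP90B1 (−1.83) and PDIA4 (−1.73) encode chaperones of the endoplasmic reticulum (ER), and SLC7A5 (−1.99) an amino acid transporter. Epithelial-mesenchymal and liver stem markers were lower in 15 of 26 and higher in 4 (the same adjusted over the list alone; median −0.62; adjusted p = 0.00572, and adjusted p = 0.14 with an estimated correlation). ANPEP stood at −1.99 and TGFB1, which shares 6.6% of its exon bases with HNRNPUL1, at −2.03 against ZEB1 at 1.83. Cytosolic ribosomal protein genes were higher in 28 of 57 and lower in 13 (29 and 13 adjusted over the list alone; median 0.45; adjusted p = 0.0211, and adjusted p = 0.858 with an estimated correlation). RPL23 (2.004) and RPL15 (1.66) were among them, as were RPL26 (2.33) and RPS23 (2.06), which overlap other genes and are uncertain.

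HuR targets drawn from the literature did not pass camera in the WT enrichment (adjusted p = 0.388), but passed fry, which does not compare them with other genes, in the downward direction (adjusted p = 0.00737). Of 35 tested, 6 were higher and 9 lower (6 and 8 adjusted over the list alone; median −0.07), and ACTB (−1.74), MTA1 (−1.50) and EGFR (−0.92) were among the lower ones. The other 13 lists did not pass camera either. Their counts of higher and lower members were 5 and 6 of 28 for cell cycle arrest genes (adjusted p = 0.295), 7 and 5 of 21 for senescence-associated secreted factors (adjusted p = 0.925), 6 and 13 of 31 for S phase (adjusted p = 0.114) and 6 and 13 of 34 for G2 and M phase (adjusted p = 0.191). They were 9 and 3 of 22 for the SUMO pathway (adjusted p = 0.346), 13 and 8 of 34 for RNA-binding proteins (adjusted p = 0.541), 5 and 6 of 27 for apoptosis regulators (adjusted p = 0.951) and 16 and 14 of 41 for the nuclear-encoded respiratory chain (adjusted p = 0.898). For mitochondrially encoded mRNAs they were 6 and 1 of 13 (adjusted p = 0.183), for replication-dependent histones 4 and 11 of 18 (adjusted p = 0.183) and for abundant structural RNAs 3 and 7 of 19 (adjusted p = 0.115). Markers of cell types that a pure line should not hold were tested in few members: 2 and 3 of 11 for immune cells (adjusted p = 0.925) and 1 and 4 of 7 for stromal and endothelial cells (adjusted p = 0.476). These counts were the same adjusted over the list alone, except stromal markers (1 and 5). Of these 13, fry called cell cycle arrest (adjusted p = 0.000225), S phase (0.000798), G2 and M phase (0.00138) and stromal genes (0.00172) downward and the SUMO pathway upward (0.00737). Immune markers had a median of −0.48, a mean of 0.20 and a test direction upward, and apoptosis regulators a median of −0.04, a mean of 0.01 and a test direction downward.

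In all, 5875 of 22984 genes were higher and 5835 lower in WT RIP than in WT input by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the split became 15761 higher and 879 lower with total library size. Changes moved with base composition, with a median of 0.16 in GC-poor coding genes, −0.06 in those of middle GC content and −0.72 in GC-rich ones (3 groups of equal size by transcript GC). The hepatocyte, glycolytic, stress, marker, ribosomal and noncoding lists each passed again with the GC trend removed, a setting chosen after seeing the data. G2 and M phase genes then passed as well (median −0.27, adjusted p = 0.00722).

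The mutant precipitate was compared with its own input in the same way, and the RNAs at both ends were largely those of the WT line. SCARNA7 (6.78 ± 0.64), SNORD6 (6.65 ± 0.29), SNORD14E (5.70 ± 0.30), MIR3609 (5.69 ± 0.40) and SNORA41 (5.39 ± 0.51), uncertain as it lies in exons of EEF1B2, led the noncoding genes, and 213 of 302 snoRNAs were higher and 28 lower (median 2.38). The leading coding genes included XKR9 (4.31 ± 0.24), LRRC37A (4.26 ± 0.23), LRRC37A2 (4.12 ± 0.21) and MAN1A2 (3.798 ± 0.17). The lowest were PLBD2 (−3.76 ± 0.15), WDR74 (−3.74 ± 0.34), APOE (−3.66 ± 0.18), CHST13 (−3.53 ± 0.21) and COL6A1 (−3.501 ± 0.23), followed by IGSF8, clusterin (CLU), CTSD, LRPAP1 and SERPINA1 at −3.49 to −3.31. RN7SL copies again lay lowest of all (RN7SL359P, −7.48 ± 0.53). Across genes, which are not independent replicates, the fold changes of the 2 lines correlated at r = 0.84 over 22984 genes and 0.962 over the 11414 with a log2 CPM of at least 2. Both lines called 4881 genes higher, where independent lists would share 1703.4, and 5136 lower (1634.4), with 4 called in opposite directions. No library is common to these 2 comparisons.

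The same 6 lists passed camera in the mutant line. Hepatocyte genes were lower in 26 of 38 and higher in 1 (27 and 1 adjusted over the list alone; median −0.96; adjusted p = 5.38e-10, and adjusted p = 0.0128 with an estimated correlation). SERPINA1 stood at −3.31, AMBP at −2.89 and F2 at −2.43. The listed long noncoding RNAs were higher in 21 of 24 and lower in 1 (the same adjusted over the list alone; median 1.53; adjusted p = 4.09e-09, and adjusted p = 0.175 with an estimated correlation). CRNDE stood at 2.24, NEAT1 at 1.66 and SNHG5 at 2.12. Stress response genes were lower in 19 of 30 and higher in 4 (20 and 4 adjusted over the list alone; median −0.55; adjusted p = 1.28e-05, and adjusted p = 0.115 with an estimated correlation). SLC7A5 stood at −2.88 and CALR at −2.65. Epithelial-mesenchymal markers were lower in 17 of 26 and higher in 2 (19 and 2 adjusted over the list alone; median −0.51; adjusted p = 0.00203, and adjusted p = 0.115 with an estimated correlation). Glycolytic genes were lower in 15 of 23 and higher in 1 (the same adjusted over the list alone; median −0.67; adjusted p = 0.00203, and adjusted p = 0.456 with an estimated correlation). Ribosomal protein genes were higher in 30 of 57 and lower in 14 (the same adjusted over the list alone; median 0.43; adjusted p = 0.0159, and adjusted p = 0.871 with an estimated correlation). HuR targets from the literature again did not pass camera (13 higher and 9 lower of 35, also adjusted over the list alone; adjusted p = 0.551) and passed fry downward (adjusted p = 0.011). The total came to 6664 genes higher and 6438 lower, which became 16795 and 922 with total library size. The median was 0.38 in GC-poor coding genes and −0.87 in GC-rich ones, and with the GC trend removed the 6 lists passed again, with G2 and M phase genes added (median −0.47, adjusted p = 0.0232).

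**Figure D2:**
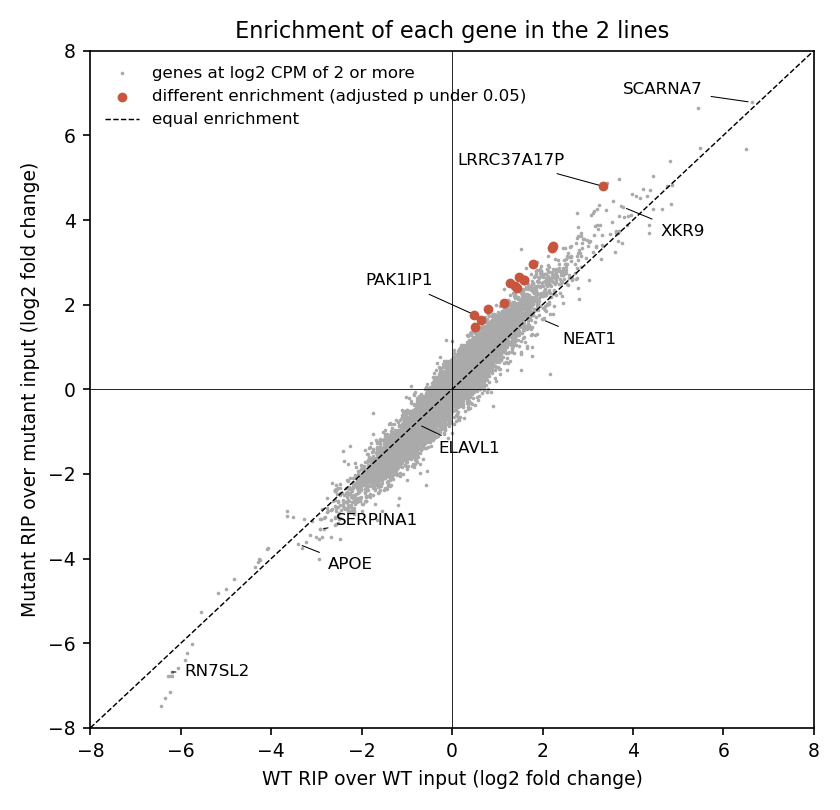
Each point is a gene with a mean log2 CPM of at least 2, placed by its log2 fold change of RIP over input in the WT line (horizontal axis) and in the mutant line (vertical axis), the dashed line marks equal enrichment, and ELAVL1 turned from below 0 to above 0 in both lines with total library size. The 15 genes whose enrichment differed between the lines are drawn larger and lie above that line, between LRRC37A17P (1.47 higher in the mutant) and DYNC1LI1 (0.89 higher).

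The study's central comparison asks whether the mutation changed which RNAs came down with HuR, and it was tested as the enrichment in the mutant minus the enrichment in WT. A larger enrichment in the mutant passed the test for 15 genes, each of which was also higher in WT RIP than in WT input. PAK1IP1, which encodes a protein of ribosome biogenesis (ENSG00000111845, chromosome 6, 10695205 to 10710015), went from 14.7 ± 2.02 CPM (SD, n = 3) in WT input to 20.5 ± 2.46 in WT RIP and from 13.0 ± 1.57 in mutant input to 44.2 ± 4.31 in mutant RIP, a difference of 1.28 ± 0.19 (adjusted p = 0.0115). CCS, the copper chaperone of superoxide dismutase, had equal inputs (54.9 CPM in each line) and stood at 166 ± 28.0 CPM in WT RIP and 330.3 ± 24.7 in mutant RIP, a difference of 0.996 ± 0.19 (adjusted p = 0.0369). The RNA-binding protein gene TSNAX (1.10 ± 0.19), the ER membrane complex gene EMC2 (1.06 ± 0.20), the histone acetyltransferase gene HAT1 (0.97 ± 0.18), the dynein gene DYNC1LI1 (0.89 ± 0.17), GOSR2, a SNARE of the Golgi (0.99 ± 0.19), SKAP2 (0.99 ± 0.19) and LRRC69 (1.18 ± 0.23) also passed, with adjusted p values of 0.0369 to 0.0424. So did the noncoding genes LRRC37A17P (1.47 ± 0.26) and LINC02484 (1.13 ± 0.22) and the readthrough gene TSNAX-DISC1 (1.24 ± 0.23). The other 3, genes without a symbol, ENSG00000267383, ENSG00000262633 and ENSG00000254673, are named here after their values were seen, to complete the set (0.95 to 1.16). The 15 genes lie at 12 separate places. Of these genes, 5 share exon bases with another of them, and ENSG00000254673 shares 88.6% of its exon bases with FNTA, so these overlapping genes are uncertain. SKAP2, singled out after its values were seen, stood at −0.32 ± 0.13 in mutant RIP against WT RIP (adjusted p = 0.0817, but past the threshold at −0.42 without WT RIP 1 and at −0.34 with the GC trend removed) and was lower in the mutant input (−1.31 ± 0.14).

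No gene passed with a smaller enrichment in the mutant by edgeR, against 1258 at an unadjusted p under 0.05 and 58 by DESeq2. For a larger enrichment the unadjusted count was 1747 and DESeq2's count 331. Of the HuR targets from the literature, 0 passed over all genes by edgeR (3 higher and 4 lower at an unadjusted p under 0.05, 2 higher and 0 lower by DESeq2), and 1 was higher adjusted over the list alone (median 0.01; camera adjusted p = 0.99). By fry the list had an adjusted p of 0.846 for a move in 1 direction and 0.00914 for changes in either direction. The latter was not particular to HuR targets. Other lists passed it too, among them epithelial-mesenchymal markers (0.0011), RNA-binding proteins (0.00225) and cell cycle arrest genes (0.00297). CCNB1 (0.69 ± 0.18, adjusted p = 0.109), CDKN1A (−0.70 ± 0.21, adjusted p = 0.152) and CTNNB1 (0.54 ± 0.17, adjusted p = 0.175) had the smallest p values among the HuR targets. Of the lists, 4 passed camera, with 0 members past the gene test by edgeR. Senescence-associated secreted factors had a median of −0.22 (21 tested), hepatocyte genes −0.13 (38) and stress response genes −0.10 (30), all toward a smaller enrichment in the mutant, and S phase genes 0.11 (31), toward a larger one. Between the inputs, the medians of the senescence-associated (0.41), stress response (0.37) and S phase lists (−0.32) lay in the opposite direction. That of the hepatocyte list (−0.06) lay in the same direction. For the difference of enrichments, the camera adjusted p was 0.0204 for each of the 4, and adjusted p = 0.374 for each with an estimated correlation. At an unadjusted p under 0.05, 3 senescence-associated, 5 hepatocyte and 5 stress response members were lower and 5 S phase members higher, and DESeq2 called 0, 1, 2 and 1 of these. Adjusted over the list alone, 1 stress response gene was lower and 0 members of the other 3 lists passed. Outside these lists, members passing when adjusted over the list alone were most frequent among RNA-binding proteins, 5 higher and 3 lower of 34 (list adjusted p = 0.32). TIAL1 stood at 0.73 ± 0.18 and ZFP36 at −0.83 ± 0.24, neither past the test over all genes. The count of 15 larger enrichments was 1 with a stricter count filter (the other 14 each at an adjusted p of 0.0546), 0 without WT RIP 1 or mutant RIP 3 (unadjusted 1310 and 1487), 1 without mutant RIP 2, WT input 1, WT input 2 or mutant input 1, 3 without mutant input 2, 5 without mutant input 3, 7 without WT RIP 2, 18 without mutant RIP 1 (all 15 among them), 56 without WT RIP 3 and 59 without WT input 3. The 1 gene called without WT input 1 was not among the 15, and of the 5 called without mutant input 3, 3 were. Tested against the WT enrichment scaled by its slope across abundant genes (1.192), 0 of the 15 passed by edgeR (15 at an unadjusted p under 0.05). That test was chosen after seeing the data, and 74.1% (SD 5.5 across genes, not libraries) of the 15 genes' median difference was left. In 7 of 100 splits of the libraries, the real one included, there were at least 15 calls, and 5 of the 6 others kept the lines apart in precipitates or inputs and so hold the line difference. The median difference of coding genes ran from 0.22 in the GC-poor group to −0.15 in the GC-rich group.

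**Figure D3:**
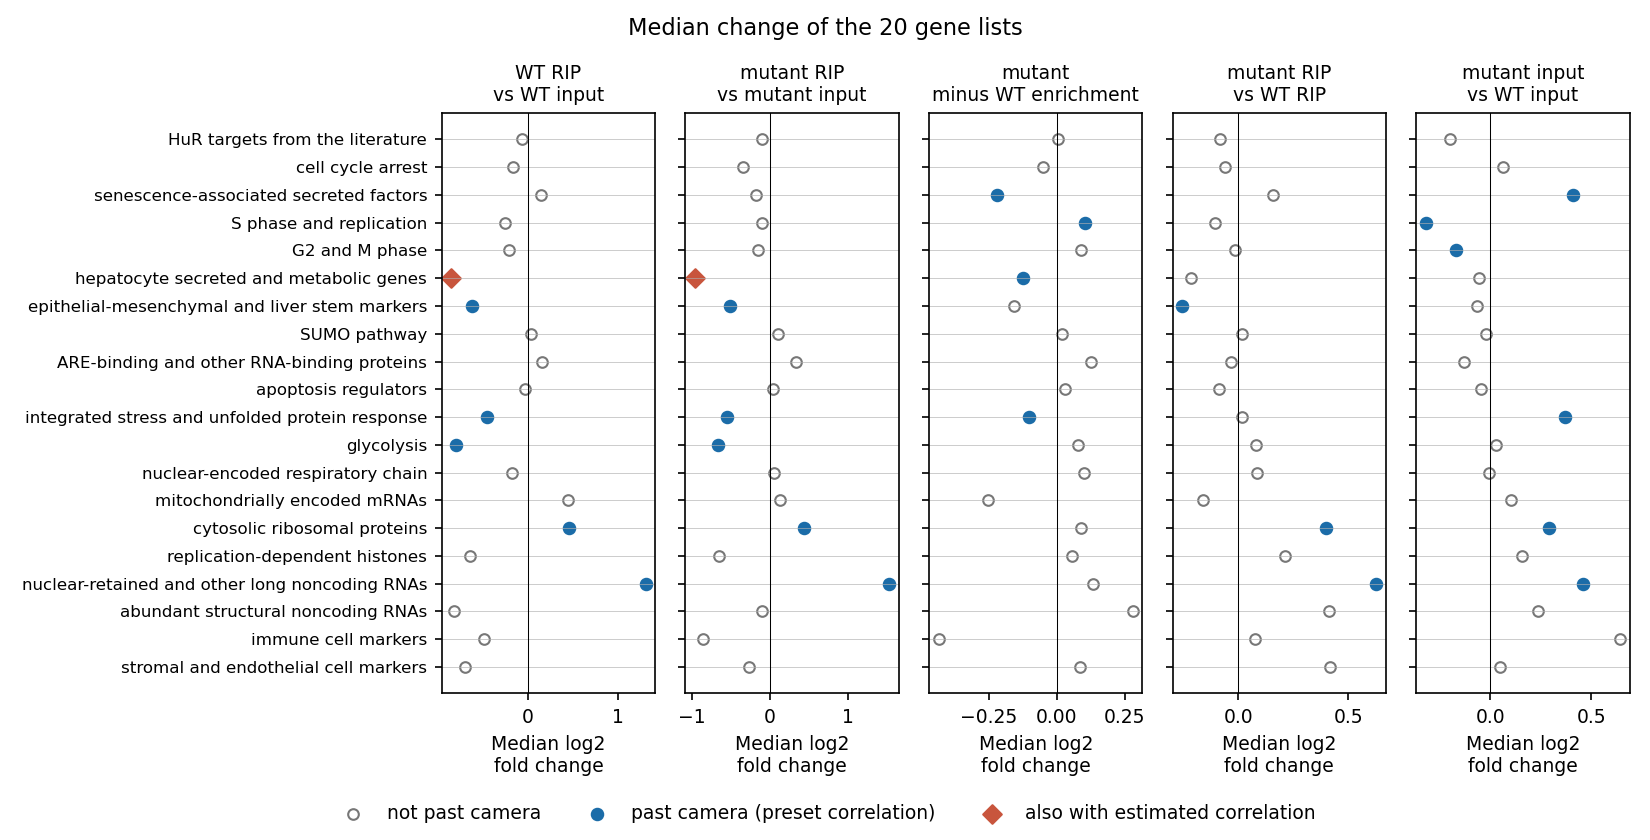
For each of the 20 gene lists (vertical axis), the median log2 fold change of its tested members is shown in each of the 5 comparisons (panels with their own horizontal scales). Filled points passed camera with the preset correlation and red diamonds also with an estimated correlation, which holds for the hepatocyte list in the 2 enrichments (medians −0.85 and −0.96, relative to the typical gene, which total library size moves to 1.12 and 1.38).

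The mutant and WT precipitates were also compared directly, which sets side by side the RNAs recovered in each line without regard to their input level. PAQR5, a membrane progestin receptor (ENSG00000137819, chromosome 15, 69591251 to 69700119), was at 11.8 ± 0.723 CPM (SD, n = 3) in mutant RIP and 1.69 ± 0.101 in WT RIP (2.798 ± 0.16, adjusted p = 3.91e-11), and it shares 12.7% of its exon bases with KIF23-AS1. The drug-metabolizing cytochrome CYP2C19 (2.62 ± 0.18), TMEM45B (1.96 ± 0.19), the protease inhibitor alpha-2-macroglobulin (A2M, 1.72 ± 0.20), RCN1 (1.61 ± 0.14), TSPAN8 (1.58 ± 0.13) and the calcium-binding protein S100P (1.48 ± 0.18) were also higher in the mutant. CYP2C19 has close paralogs that can share its reads. Lower in the mutant were PWWP3B (−2.30 ± 0.17), the lysosomal protease cathepsin F (CTSF, −2.13 ± 0.17), the actin-bundling protein FSCN1 (−2.01 ± 0.20), the chemokine CXCL1 (−1.999 ± 0.20), the metallothionein MT1F (−1.84 ± 0.19) and SERPINA5 (−1.83 ± 0.12). LINC02972 led the noncoding genes (3.02 ± 0.20), and 52 of 302 snoRNAs were higher, with 0 lower by edgeR (94 and 2 at an unadjusted p under 0.05, 70 and 0 by DESeq2). In all 2268 genes were higher and 2244 lower, and total library size gave 776 and 2529.

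Between the precipitates, 3 lists passed camera and none of the 3 with an estimated correlation. Ribosomal protein genes were higher in 20 of 57 with 0 lower by edgeR (24 and 0 adjusted over the list alone; median 0.40; adjusted p = 9.34e-09, and adjusted p = 0.597 with an estimated correlation). RPS24 stood at 0.78, RPLP0 at 0.88 and RPL34 at 0.79. At an unadjusted p under 0.05 they were 36 and 0, and by DESeq2 32 and 0. The listed nuclear-retained and other long noncoding RNAs were higher in 13 of 24 and lower in 2 (13 and 3 adjusted over the list alone; median 0.63; adjusted p = 1.15e-06, and adjusted p = 0.451 with an estimated correlation), among them the snoRNA host GAS5 (1.39 ± 0.17), PVT1 (1.56 ± 0.20), FTX (1.18 ± 0.16) and EPB41L4A-AS1 (1.23 ± 0.14), of which FTX shares 28.0% of its exon bases with JPX and EPB41L4A-AS1 51.2% with EPB41L4A, so both are uncertain. Of the whole class of 4523 long noncoding RNAs, 286 were higher and 199 lower (median 0.02). Epithelial-mesenchymal markers were lower in 10 of 26 and higher in 3 (12 and 4 adjusted over the list alone; median −0.26; adjusted p = 0.0102, and adjusted p = 0.451 with an estimated correlation). PROM1 stood at −0.96, CCN1 at −1.09 and CDH2 at −0.70. Among HuR targets from the literature 9 were higher and 5 lower of 35 (9 and 6 adjusted over the list alone; adjusted p = 0.677), including EGFR (−0.997 ± 0.11), the chemokine gene CXCL8 (−1.57 ± 0.26) and VEGFA (0.49 ± 0.11). Without WT RIP 1 the count of higher genes was 1299, and without mutant RIP 2 the counts were 1505 higher and 1448 lower. The 3 GC groups had medians of −0.02, −0.04 and −0.03, and the 3 lists passed with the GC trend removed.

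The inputs show how the 2 lines differed in RNA level before precipitation. PAQR5 (2.82 ± 0.17), CYP2C19 (2.62 ± 0.21), TMEM45B (2.44 ± 0.20), A2M (2.38 ± 0.20), the water and glycerol channel AQP3 (1.77 ± 0.18) and S100P (1.67 ± 0.19) were higher in the mutant line. Lower were CTSF (−2.44 ± 0.16), PWWP3B (−2.42 ± 0.18), MT1F (−1.84 ± 0.19), TFEC (−1.83 ± 0.16), ANXA3 (−1.78 ± 0.13) and the bile acid synthesis enzyme AKR1D1 (−1.72 ± 0.15). CTSF (ENSG00000174080, chromosome 11, 66330935 to 66336350) was at 17.1 ± 1.12 CPM (SD, n = 3) in WT input and 3.15 ± 0.549 in mutant input. CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36644237 to 36655114), rose from 5.90 ± 0.68 CPM to 14.6 ± 2.21 (1.31 ± 0.15, adjusted p = 2.06e-06). Also higher were the kinase gene PLK2 (1.45 ± 0.19), the mTOR inhibitor gene DDIT4 (1.58 ± 0.17), MYC (0.84 ± 0.12) and DUSP1 (1.06 ± 0.16). In all 1716 genes were higher and 2301 lower, and total library size gave 386 and 6822.

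Between the inputs, 6 lists passed camera and none of the 6 with an estimated correlation. S phase genes were lower in 12 of 31 and higher in 1 (16 and 1 adjusted over the list alone; median −0.32; adjusted p = 2.59e-05, and adjusted p = 0.318 with an estimated correlation). RRM2 stood at −0.76, MCM6 at −0.66 and CCNE2 at −1.02, and CCNE2, which shares 37.0% of its exon bases with INTS8, is uncertain. G2 and M phase genes were lower in 8 of 34 and higher in 1 (9 and 1 adjusted over the list alone; median −0.17; adjusted p = 0.0197, and adjusted p = 0.512 with an estimated correlation). HMMR stood at −0.80 against FOXM1 at 0.59, which is uncertain for the 15.9% of exon bases it shares with ITFG2. Senescence-associated secreted factors were higher in 6 of 21 and lower in 3 (7 and 3 adjusted over the list alone; median 0.41; adjusted p = 0.0235, and adjusted p = 0.318 with an estimated correlation). IGFBP4 (1.61 ± 0.29) and VEGFA (0.60 ± 0.11) rose, and CXCL1 (−1.50 ± 0.21) fell. Stress response genes were higher in 13 of 30 and lower in 2 (16 and 5 adjusted over the list alone; median 0.37; adjusted p = 0.000586, and adjusted p = 0.318 with an estimated correlation). DDIT3 stood at 0.86 and SLC3A2 at 0.59, and DDIT3, which shares 27.2% of its exon bases with MARS1, is uncertain. Ribosomal protein genes were higher in 11 of 57 with 0 lower by edgeR (the same adjusted over the list alone; median 0.29; adjusted p = 1.18e-06, and adjusted p = 0.631 with an estimated correlation), with 25 and 0 at an unadjusted p under 0.05 and 23 and 0 by DESeq2. The listed long noncoding RNAs were higher in 12 of 24 and lower in 1 (the same adjusted over the list alone; median 0.46; adjusted p = 9.2e-05, and adjusted p = 0.512 with an estimated correlation), against 217 higher and 184 lower in the whole class of 4523. GAS5 stood at 1.18 and SNHG8 at 1.17 against TUG1 at −0.83, and SNHG8, which shares 37.6% of its exon bases with PRSS12, is uncertain. The list of cell cycle arrest genes did not pass camera (4 higher and 7 lower of 28, 8 and 7 adjusted over the list alone; adjusted p = 0.883). Nor did the HuR targets from the literature, to which CDKN1A, MYC, DUSP1 and VEGFA belong (camera adjusted p = 0.675). Of 35 tested, 6 were higher and 10 lower (7 and 11 adjusted over the list alone), with a median of −0.20.

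Base composition moved with these input differences: the median was −0.24 in GC-poor coding genes, −0.07 in those of middle GC content and 0.11 in GC-rich ones. With the GC trend removed, the G2 and M phase list (median −0.04, adjusted p = 0.427) and the senescence-associated secreted factors (median 0.44, adjusted p = 0.0752) no longer passed, while S phase, stress response, ribosomal protein and long noncoding RNA lists did. Without WT input 1 the counts were 964 genes higher and 1231 lower. Of the 4017 genes called between inputs, 3640 (90.6%) had the same sign between the precipitates. Both comparisons called 864 genes higher (169.3 shared by independent lists) and 1188 lower (224.7), with 10 in opposite directions, and the correlation across genes, which are not independent replicates, was r = 0.461, or 0.66 over abundant genes. No library is common to these 2 comparisons.

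**Figure D4:**
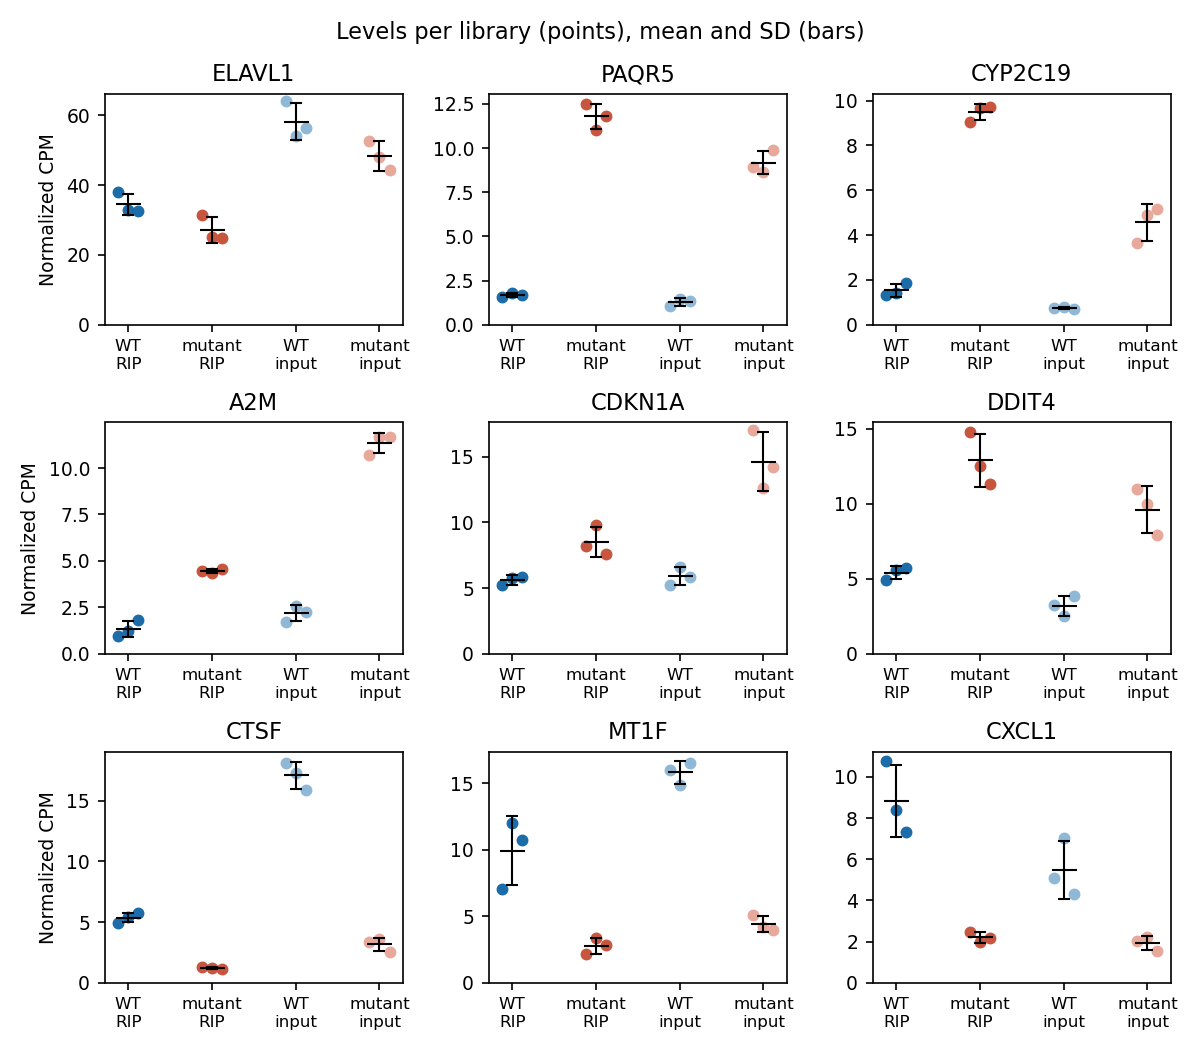
Normalized CPM of 9 genes, with each library as a point and the mean and SD of the 3 libraries of a group as bars. PAQR5 stands at 11.8 CPM in mutant RIP and 9.16 in mutant input against 1.69 and 1.30 in the WT line, CTSF at 17.1 in WT input against 3.15 in mutant input, and ELAVL1 lies lower in the precipitates (34.5 and 27.2) than in the inputs (58.2 and 48.4), an order that turns with total library size.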

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

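The tests below on the genes and lists whose enrichment differed between the lines, and on the line differences shared by precipitates and inputs, were chosen after the results were seen, as was the way the libraries were split for the difference of enrichments.

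The enrichment in the mutant line exceeded that in the WT line by a test of the difference itself for 15 genes, in log2 units: LRRC37A17P 1.467, PAK1IP1 1.279, TSNAX-DISC1 1.236, LRRC69 1.18, ENSG00000267383 1.158, ENSG00000262633 1.151, LINC02484 1.128, TSNAX 1.098, EMC2 1.058, CCS 0.996, GOSR2 0.993, SKAP2 0.987, HAT1 0.972, ENSG00000254673 0.95 and DYNC1LI1 0.894. By camera, the difference also passed for senescence-associated secreted factors (median −0.221), S phase genes (0.105), hepatocyte genes (−0.125) and stress response genes (−0.101), none of which passed with an estimated correlation (adjusted p = 0.374).

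For the 15 genes, a GC-dependent difference between the libraries of the 2 lines is argued against as the whole cause, because 14 of 15 kept an adjusted p under 0.05 with the GC trend removed (SKAP2 had 0.0791). A stronger overall enrichment in the mutant precipitations stays open: tested against the WT enrichment scaled by the slope over abundant genes (1.192), 0 of the 15 passed by edgeR (15 at an unadjusted p under 0.05), as their median difference went from 1.098 (median SE 0.191) to 0.814 (median SE 0.21). A lower RNA level in the mutant input alone would leave no rise between the precipitates, and 14 genes were each also higher in mutant RIP than in WT RIP. HAT1 was so by 0.458, with −0.514 between inputs. It fell short of the threshold at 0.389 without WT RIP 1, 0.418 without mutant RIP 3 and 0.273 with total library size. The precipitate difference is part of the difference these genes were called on. Their rise was favored by that choice and is no independent evidence against a lower input. SKAP2, set apart after its values were seen, stood at −1.306 between inputs and −0.319 between precipitates, so it had a lower input and no rise between precipitates. A lower RNA level recovered in the same proportion would lower both alike, so these values do not settle the cause for SKAP2. A changed recovery with the mutant protein, or another difference between the 2 lines, stays open and untested, and with a stricter count filter 1 of the 15 was called and the other 14 just missed it, each with an adjusted p of 0.0546 (3.09e-08 to 0.0791 over the alternatives that keep all libraries), with a median difference of 1.087 in place of 1.078. For the 4 lists, the GC trend is argued against in the same way, as 4 of 4 passed with it removed. A different RNA level in the mutant input was not tested for the lists and stays open. Median differences between inputs and between precipitates were −0.32 and −0.105 for S phase genes and 0.368 and 0.014 for stress response genes. They were 0.411 and 0.157 for senescence-associated secreted factors and −0.057 and −0.216 for hepatocyte genes.

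Both precipitations recovered largely the same RNAs above and below input. All RIP libraries were made from less RNA than the inputs, and an effect of that amount cannot be told apart from precipitation. The SDs, the SE and the permutation p-values that follow measure the spread between genes, not between libraries. GC content as the whole cause is argued against by the 75% of called coding genes that stayed called in the same direction in WT with the GC trend removed. A preference for U over A in 3' UTRs is argued against by the partial rho of the U share with WT enrichment across genes, which are not independent replicates (−0.054, SD 0.01), but U runs and ATTTA motifs had raw rho of 0.23 and 0.331 and partial rho of −0.038 and 0.02 given GC and lengths, so AU-rich elements are not separated from GC content. Loss of mRNAs held at the ER may contribute, because coding genes with a hydrophobic N-terminal segment were lower by −0.346 log2 units (SE 0.02) than others given GC and lengths. Nuclear unspliced RNA and unspliced host RNA cannot be told apart from reads of the nested genes themselves: pseudogenes in introns on the host's strand differed by −0.179 (SD 0.13, two-sided permutation p = 0.0768) in WT and −0.294 (SD 0.121, p = 0.0162) in the mutant from those on the opposite strand, and nested ones by 0.325 (SD 0.067) in WT from those outside genes, but the strand setting is not stated and such counts can be reads of a parent gene.

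Differences between the lines were shared by precipitates and inputs. Over the 4017 genes called between inputs, the precipitate difference was a median of 0.68 of the input difference (SD 0.0098 across genes, not libraries). Such a ratio goes with RNA level in the 2 lines contributing to the precipitate difference of these genes. It does not give the share of the precipitate differences that RNA level sets, and 2052 of the 4512 genes called between precipitates were also called between inputs with the same sign. Whether the lines differ because of the mutation or because they are separate stable lines cannot be tested with 1 line of each.

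For the comparisons of 2 groups, each set of 6 libraries has 10 splits into 3 and 3, too few for a share under 0.05, and 1 of 10, the real one, gave as many calls in each. The real counts and the highest of the other splits were 11710 and 0 for the WT enrichment, 13102 and 0 for the mutant enrichment, 4512 and 34 between precipitates, and 4017 and 1 between inputs. For the difference of enrichments, the precipitates and the inputs were split independently. Of 100 splits drawn from 200, 7 gave at least the real 15 calls, the real one included, so chance is not excluded. This is no clean share for chance, since the highest of the others gave 1502, which points to a structure of the samples: 5 of the 6 others with at least 15 calls kept the lines apart in either the precipitates or the inputs. Those 5 hold the line difference. Of the 82 others that mixed the lines in both, 1 gave as many, but mixing adds the line difference to the spread within groups.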

How the results depend on the processing

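The settings with the GC trend removed and with coding genes only were chosen after seeing the data. Of 8836 values of 516 named results under the alternatives, 8396 stayed on their side of the threshold, 337 no longer passed it and 81 newly passed it. The other 22 reversed, changing sign while past the threshold in the main or the alternative setting. The 8396 include any result that changed sign while passing in neither setting. Where a result moved, the cause was not tested unless stated. A fold limit, which by construction calls fewer genes, gave 3364 higher and 2511 lower in the WT enrichment, 4118 and 3413 in the mutant, 9 higher in the difference, 560 and 421 between precipitates and 551 and 383 between inputs. Total library size gave 15761 and 879, 16795 and 922, 96 and 9, 776 higher between precipitates, and 386 and 6822 between inputs, where the shift of the median gene is part of the setting. Coding genes only, with fewer genes tested, gave 3866 higher in WT, 4420 higher in the mutant and 55 and 2 in the difference. For the difference of enrichments the counts were also 24 and 1 with protein-coding normalization, 119 and 66 with no filter, 1 higher with the strict filter, 23 higher with the replicate block, 86 and 19 with the block within line, 34 and 15 with the GC trend removed and 331 and 58 by DESeq2. Whether replicate numbers pair the samples is not settled, so both blocks are only alternatives. Between the 2 precipitates, same-number correlations were 0.363, 0.596 and 0.042, and between the inputs −0.341, 0.162 and −0.51. Between precipitate and input they were 0.293, 0.151 and −0.165 in WT and 0.294, −0.034 and 0.411 in the mutant.

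Lists past the test numbered 1, 1, 0, 0 and 0 over the 5 comparisons with an estimated correlation (at an unadjusted p under 0.05, 4, 4, 1, 1 and 3) and 11, 12, 0, 8 and 10 by fry (12, 13, 7, 8 and 10). They numbered 7 in the difference with the GC trend removed, and between precipitates 6 with total library size and 5 with the replicate block. ELAVL1 went from −0.76 to 0.295 in WT and from −0.83 to 0.492 in the mutant with total library size, which also took the input difference past the threshold (−0.717), and the precipitate difference passed with the replicate block (−0.344) and the GC trend removed (−0.342). Total library size also reversed EGFR 0.152, RB1 0.331, TPX2 0.269, PTBP1 0.126, CASP2 0.232, TNFRSF10B 0.403, CD68 0.271, LYZ 0.456, PDGFRA 0.63 and COL1A2 0.187 in WT, and SESN2 0.211, TNFRSF1A 0.283, CDC25B 0.018, SOX9 0.104, TNFRSF10B 0.2, BIRC5 0.537, MT-ND5 0.685, CD68 0.401, LYZ 0.885, COL1A2 0.27, PDGFRA 0.862 and PDGFRB 0.204 in the mutant, all below 0 with TMM.

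Leaving out 1 library gave 5121 to 5602 higher and 5046 to 5518 lower in WT, 6050 to 6345 and 5881 to 6197 in the mutant, 0 to 59 and 0 to 16 in the difference, 1299 to 2183 and 1448 to 2125 between precipitates, and 964 to 1563 and 1231 to 2194 between inputs. Higher counts in the difference were 0 without WT RIP 1 or mutant RIP 3, 1 without mutant RIP 2, WT input 1, WT input 2 or mutant input 1, 3 without mutant input 2, 5 without mutant input 3, 7 without WT RIP 2, 18 without mutant RIP 1, 56 without WT RIP 3 and 59 without WT input 3, and lower counts 1 without mutant RIP 1, 8 without WT RIP 3 and 16 without WT input 3. Of these higher genes, the 1 without WT input 1 was not among the 15 of the main fit, and 3 of the 5 without mutant input 3 were. Between precipitates 1299 were higher without WT RIP 1, and 1505 higher and 1448 lower without mutant RIP 2, and between inputs 964 and 1231 without WT input 1. Lists past the test ran from 6 to 7, 5 to 6, 3 to 8, 4 to 8 and 5 to 9, with 8 in the difference without WT RIP 2 and 7 without mutant RIP 1, and between precipitates 5 without WT RIP 1 or 2 and 8 without mutant RIP 1. ELAVL1 ran from −0.832 to −0.642, −0.949 to −0.765, −0.198 to 0.004, −0.461 to −0.266 and −0.33 to −0.175. ELAVL1 counts of 1087 to 3039 per library leave spread between libraries, not depth, as the limit there.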

Other observations

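Gene groups outside the comparisons' leading lists were also counted. Nuclear-encoded respiratory chain genes had 16 higher and 14 lower of 41 in the WT precipitate and 17 and 12 in the mutant, and SUMO pathway genes 9 and 3 of 22 in WT and 9 and 7 in the mutant, without either list passing camera. The SUMO pathway passed fry upward in both lines (adjusted p = 0.00737 and 0.00166). Between the inputs, the epithelial marker KRT19 (1.58), the glycolytic enzyme ALDOC (1.35) and antithrombin (SERPINC1, 1.07) were higher in the mutant line, and the urea cycle enzyme ASS1 (−0.99) and PFKL (−1.10) were lower. The lists that hold these genes did not pass camera there. Epithelial-mesenchymal markers had 3 higher and 7 lower of 26, glycolytic genes 5 and 5 of 23, and hepatocyte genes 4 and 4 of 38. Mitochondrial genes held 5.55% ± 0.898 of the counts in WT RIP and 4.38% ± 0.416 in mutant RIP, against 2.10% ± 0.154 in WT input and 2.32% ± 0.36 in mutant input (SD, n = 3), a difference between precipitates and inputs that was not tested.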
